A study of Mus musculus with 3 samples.

How the data were processed

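Single cells of 3 sorted mouse bone marrow populations were measured with 10x Chromium v2 libraries, 1 per group (ALP, ILCpro_WT and ILCpro_KO). The counts deposited by the authors are UMI counts per gene and cell barcode, and the values are whole numbers as such counts are. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.1b, Cell Ranger 2.0.1 and the mm10 genome, without giving each tool's role or the settings by which cells were called. Each table holds 27998 genes, of which 16403 had a UMI in any kept cell. Symbols were joined on Ensembl identifiers to GENCODE vM21 (GRCm38) for gene locations. The reporter EGFP and the T cell receptor constant genes are not in the gene list, so neither the reporter nor Trac, Trbc1 or Trbc2 could be read.

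The deposited barcodes numbered 812 in ALP, 1834 in ILCpro_WT and 716 in ILCpro_KO. Cells with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes were kept, which left 810, 1829 and 716. Ribosomal protein genes took 35.7%, 38.6% and 33.6% of UMIs, and the 10 most abundant genes 9.07%, 11.6% and 8.69%. A count of 3 UMIs, the floor used for bounds in each library, equals 0.729, 0.492 and 0.684 CPM. ILCpro_KO and ILCpro_WT shared 1 barcode sequence and ILCpro_WT and ALP shared 4, so the libraries are not copies of each other. Doublets were scored with Scrublet in each library. They were kept in the values reported, and an alternative removed the highest scores at 0.8% per 1000 barcodes, which took 5, 27 and 4 cells.

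UMIs were summed over the kept cells of a library and scaled to the library total (CPM). Ratios on the log2 scale used log2((CPM + 10)/(CPM + 10)), while folds are plain ratios of CPM. Intervals are exact at 95%: Poisson for sums, conditional binomial for ratios and Clopper-Pearson for shares. They cover counting error only, since cells of 1 library are not replicates. With 1 library per group there is no spread between replicates, so no test, p-value, standard error or count of changed genes was computed, and no adjustment for many tests applies. Beside a share of 0 stands the limit of 3 counts over the cells, which bounds cells with a UMI at that depth and not cells expressing the gene. A gene with 0 UMIs in 1 library has a bound against the floor, written as at least N-fold.

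The analysis fixed 26 gene lists before the data were examined, together with the comparisons, the alternatives, the cell type markers and the rule for naming genes. A list's median log2 ratio was taken over members with at least 5 CPM in either library. It was set beside 10000 random lists of the same size drawn from genes of like expression in 20 bins, and its percentile among these describes these libraries alone. Counting intervals of medians came from 1000 resamples of the counts. Members are counted as at least 2-fold higher or lower on the log2 scale with 10 CPM added. The lists are the ILC transcription factors, ILC precursor surface and effector genes, TCF/Wnt feedback, Notch pathway, E protein and Id, early lymphoid, B lineage, T lineage, NK and cytotoxic, ILC2, ILC3 and LTi, plasmacytoid DC, conventional DC, MHC class II, neutrophil and monocyte, mast cell and basophil, erythroid and megakaryocyte, stem and multipotent progenitor, macrophage, cytokine receptor, Bcl2 family, S phase, G2/M, immediate early and stress, interferon response, and sort and reporter genes.

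Genes are named by a rule. For each comparison these are the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in the higher library, leaving out ribosomal, mitochondrial and sex-linked genes and gene models. Also named are Tcf7, the 26 genes whose shares of cells were planned, up to 4 members of each list with the largest ratio in that comparison, and the 10 leading genes of a cluster. Some values of these genes are given in another comparison, or within clusters, than the one that named them.

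Shares of cells with a UMI were computed after thinning each cell at random to 1000 UMIs, a depth that 4 ILCpro_WT cells did not reach and that left these out. Beside them stand the unthinned shares and the share in a group of cells taken to lack the gene, or for Tcf7 in a group low in it. These groups were picked after the data were seen. All 3355 kept cells were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 at resolution 1.0, with 15 neighbours, 30 principal components, 2000 highly variable genes and counts scaled to 10000 per cell, with no batch integration. Markers, cell cycle, ribosomal, mitochondrial and sex-linked genes were left out of the clustering. A cluster was named for the type, among 14, with most markers at least 2-fold higher than in all other cells. It stayed unnamed with fewer than 3 such markers, when a marker of another type led its top 10 genes, or when more markers of another type were among these; the details of this rule were written after the data were seen. No annotation of cells by the authors was available. Within clusters, ILCpro_KO and ILCpro_WT were compared where each had at least 50 cells, with a list minimum of 20 CPM. Phases were called from S phase and G2/M gene scores.

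The method was tested on simulated data with libraries of the same depths. All of 100 genes with a 2-fold and 100 with a 4-fold change were found with the right direction in each comparison. With 10 CPM added, the median log2 ratios for ILCpro_KO over ILCpro_WT came out at 0.90 and 1.80, which is lower than the simulated change. The intervals held the simulated ratio in 95.8%, 96.3% and 95.2% of genes for ILCpro_KO over ILCpro_WT, ILCpro_WT over ALP and ILCpro_KO over ALP. Of 200 unchanged lists 3.5%, 2.5% and 5.0% fell outside the central 95% of random lists. The simulation drew the counts of each gene independently from a pooled profile, the model that the intervals assume. It held no joint shift of list members with the mix of cells. It therefore checks the computation and not how often real lists leave that range.

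The alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without ribosomal and mitochondrial genes, the mean of per-cell CPM, all deposited barcodes, a stricter filter (1000 genes, 5% mitochondrial), removal of doublets, cells called G1 alone, a pseudocount of 1 CPM, a list minimum of 20 CPM or none, no thinning or a depth of 500 UMIs, and other clustering settings (resolution 0.5 and 1.5, another seed, markers or cell cycle genes kept, cells thinned first). Removing the clusters of other lineages was added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.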

Results

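Messenger RNA was counted cell by cell in 3 populations sorted from mouse bone marrow (C57BL/6), with 1 library of 10x Chromium v2 chemistry each, so no difference given here has a replicate check. The ALP library holds all-lymphoid progenitors, the common lymphoid progenitor of the series, sorted as Lin- Kit+ 2B4+ a4b7- Flt3high IL-7Ra+. ILCpro_WT holds early progenitors of innate lymphoid cells (ILCs), sorted as Lin- Kit+ 2B4+ a4b7+ and positive for a reporter at Tcf7, the gene of the transcription factor TCF-1. Both come from Tcf7EGFP/+ mice, which carry the reporter on 1 allele, so "WT" means heterozygous for it. ILCpro_KO was sorted by the same gate as ILCpro_WT from Tcf7EGFPnull/- mice. After the filter 810 ALP cells, 1829 ILCpro_WT cells and 716 ILCpro_KO cells were kept, with 4115605, 6094683 and 4384061 UMIs (unique transcript counts). The median cell had 4544.5, 2897 and 5309 UMIs and 1803, 1194 and 1991 genes in the same order, so ILCpro_WT cells were the shallowest. Levels are UMIs scaled to the library total (CPM) with exact 95% Poisson intervals in parentheses, ratios have exact conditional binomial intervals, and all of these cover counting error only.

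Tcf7 itself (ENSMUSG00000000782, GRCm38 chromosome 11, 52252371 to 52283014, minus strand) stood at 1.46 CPM (0.535 to 3.17) in ALP, 362 CPM (347 to 378) in ILCpro_WT and 57.3 CPM (50.4 to 64.8) in ILCpro_KO. The labels do not say which part of the gene the null alleles lack, and 3' tags from outside that part check nothing. The 251 Tcf7 UMIs of ILCpro_KO therefore speak neither for nor against the genotype. With every cell thinned to 1000 UMIs, a Tcf7 UMI was found in 27.9% (exact Clopper-Pearson 25.8 to 30.01) of ILCpro_WT cells, 6.98% (5.23 to 9.10) of ILCpro_KO cells and 0.247% (0.0299 to 0.889) of ALP cells. Without thinning these shares were 54.3%, 22.2% and 0.741%. For comparison, the conventional DC-like cells of the same libraries had a Tcf7 UMI after thinning in 1.15% (0.0291 to 6.24) of 87 ILCpro_WT cells and 0.602% (0.0153 to 3.31) of 166 ILCpro_KO cells. These cells passed a gate positive for the Tcf7 reporter, so they cannot be taken to lack the gene. Their median depths before thinning were 3141 and 6546 UMIs, against 2897 and 5309 in the whole libraries.

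ILCpro_KO against ILCpro_WT asks how progenitors from the same gate differ when Tcf7 is lost. Genes of the ILC programme were lower in ILCpro_KO, and genes of neutrophils, monocytes and antigen-presenting cells were higher. Tox2, a relative of the ILC regulator Tox, was 16.4-fold lower (12.6 to 21.6), at 13.5 against 220.2 CPM. Rora, a nuclear receptor needed for group 2 ILCs (ILC2), was 9.33-fold lower (8.11 to 10.8), and Zbtb16 (chromosome 9, 48654297 to 48836222), whose product PLZF marks committed ILC precursors, was 5.35-fold lower (4.64 to 6.18). Il7r, the interleukin 7 receptor chain on which lymphoid progenitors depend, was 10.3-fold lower (7.49 to 14.5), at 9.35 against 96.1 CPM. In the other direction, Elane and Mpo, granule enzymes of neutrophil precursors, were 13.0-fold (11.6 to 14.7) and 7.22-fold (6.59 to 7.93) higher.

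The 14 measured ILC transcription factors had a median log2 ratio of -1.78 (counting interval -1.88 to -1.65), below all of 10000 random lists of like expression, whose central 95% ran from -0.05 to 0.31. The median of all genes was 0.09. Of these factors 9, with Tcf7 itself among them, were at least 2-fold lower and 0 at least 2-fold higher. Gata3, needed for ILC and T cell development, stood at 75.3 CPM (67.4 to 83.8) against 339 (325 to 354). Id2, which restrains E proteins in ILC precursors, stood at 671 (647 to 695) against 711 CPM (689.8 to 732), a small difference whose sign changed with the stricter filter and without other lineages, and Nfil3, an early regulator of ILC fate, stood at 153 (141 to 165) against 73.3 CPM (66.7 to 80.5). The 14 measured ILC precursor surface and effector genes had a median of -0.76, again below all random lists, with 4 at least 2-fold lower, among them Pdcd1 at 26.7 against 123 CPM and Icos at 3.42 against 33.8 CPM. Arg1, an enzyme found in ILC2, had 3 UMIs in ILCpro_KO and was 52.3-fold lower (17.7 to 255). ILC2 genes had a median of -1.71 over 5 members, of which 3 were at least 2-fold lower. With no list minimum that median was -0.11 over 9 members. ILC3 and lymphoid tissue inducer (LTi) genes had a median of -0.62 over 5 members, and it was 0.31 in cells called G1, -0.047 as a mean of per-cell CPM and -0.055 with no list minimum. Ltb, a cytokine of LTi cells, stood at 45.2 against 167 CPM, whereas Il1r1 stood at 29.7 against 7.22 CPM.

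Among genes outside these lists that were lower in ILCpro_KO were Fgf3, a growth factor, at 2.05 against 141 CPM, 68.7-fold lower (36.0 to 151), and Bcas1 at 4.11 against 141 CPM, 34.3-fold lower (21.6 to 58.1). Cacna1e, Igfbp7, Txk, a kinase of T and NK cells, and Rxrg, a retinoid receptor, were 42.0-fold, 28.6-fold, 17.5-fold and 8.63-fold lower. Lmo4, a transcriptional cofactor, stood at 99.5 against 595 CPM, and Ccl5, a chemokine, at 255 against 1267 CPM. Hes1, a target of Notch signalling, stood at 7.76 against 46.9 CPM, the single Notch pathway gene of 5 measured that was at least 2-fold lower. The median of that list was 0.31 and its mean -0.07.

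Neutrophil and monocyte genes had a median log2 ratio of 2.45 (2.35 to 2.53), above all random lists, with 12 of 15 at least 2-fold higher. S100a8 and S100a9, which form the calcium-binding protein calprotectin, stood at 429 against 1.64 CPM and at 251 against 0.328 CPM, the latter from 2 UMIs in ILCpro_WT (765-fold, 211 to 6322). Ngp and Camp, proteins of neutrophil granules, had 0 UMIs in ILCpro_WT and were at least 219-fold and 179-fold higher, against a floor of 3 UMIs in that library. Lyz2, the lysozyme of macrophages and granulocytes, was 10.7-fold higher (9.54 to 11.9), Ms4a3 17.2-fold, Ctsg 7.20-fold and Ly6c2 7.99-fold. Prg2, an eosinophil granule protein, had 1 UMI in ILCpro_WT and was 817-fold higher (146 to 32341). Mast cell and basophil genes (median 0.87, 2 of 8 at least 2-fold higher) included Prss34 at 297 against 77.9 CPM and Mcpt8 at 350.1 against 118 CPM. Erythroid and megakaryocyte genes (median 0.77, 4 of 10) included the haemoglobin gene Hba-a1 at 91.5 against 6.89 CPM. With the list minimum at 20 CPM these 2 medians were 1.49 and 1.78, and with a pseudocount of 1 CPM 1.83 and 1.51. The first was 1.67 in G1 cells, and the second 1.39 as a mean of per-cell CPM. A share of 16.5% of ILCpro_KO cells lay in clusters of other lineages, against 1.75% in ILCpro_WT. Without them, an alternative chosen after seeing the data, the neutrophil and monocyte median was 1.21, the erythroid median -0.41 and the mast cell and basophil median 0.43. The log2 ratio was then 1.12 in place of 5.24 for S100a8, 0.92 in place of 4.66 for S100a9, 0.54 in place of 3.83 for Prg2, 0.32 in place of 3.56 for Ngp and 0.36 in place of 3.30 for Camp. For Elane it was 1.75 in place of 3.47, for Mpo 1.58 in place of 2.72 and for Hba-a1 -0.13 in place of 2.59, while the median of the ILC transcription factors was -1.94.

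MHC class II genes, which present antigen, had a median of 0.94 (0.76 to 1.17), with 4 of 9 at least 2-fold higher. H2-Aa stood at 124 against 35.3 CPM, H2-Ab1 at 129 against 50.04 CPM, H2-Eb1 at 65.9 against 22.6 CPM, and Cd74 (chromosome 18, 60803848 to 60812652), the class II invariant chain, at 397 (378 to 416) against 139.8 CPM (131 to 149.5). Conventional dendritic cell (DC) genes had a median of 0.55 over 9 members, with Flt3, the receptor tyrosine kinase of lymphoid and DC progenitors, at 67.7 against 17.6 CPM and Ifi30 at 38.5 against 13.9 CPM. With no minimum on expression that median was 0.29. Plasmacytoid DC genes had a median of 0.66, with Irf8, a DC and monocyte regulator, at 833 against 315 CPM. Their defining gene Siglech had 2 UMIs in ILCpro_KO and 3 in ILCpro_WT. Early lymphoid genes had a median of 0.41, with 3 of 11 at least 2-fold higher: Flt3, Mef2c at 448 against 206 CPM and Dntt, the enzyme that adds nucleotides to antigen receptor joints, at 80.3 against 30.5 CPM. T lineage genes had a median of 0.17 over 10 members that went both ways, Cd3d at 51.1 against 2.79 CPM and Bcl11b, a T and ILC regulator, at 16.7 against 89.3 CPM. Of the 224 Cd3d UMIs of ILCpro_KO 205 lay in the 22 cells of T cell-like cluster 14. Without other lineages the T lineage median was -0.295 and the log2 ratio of Cd3e 0.18 in place of 1.68.

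**Figure D1:**
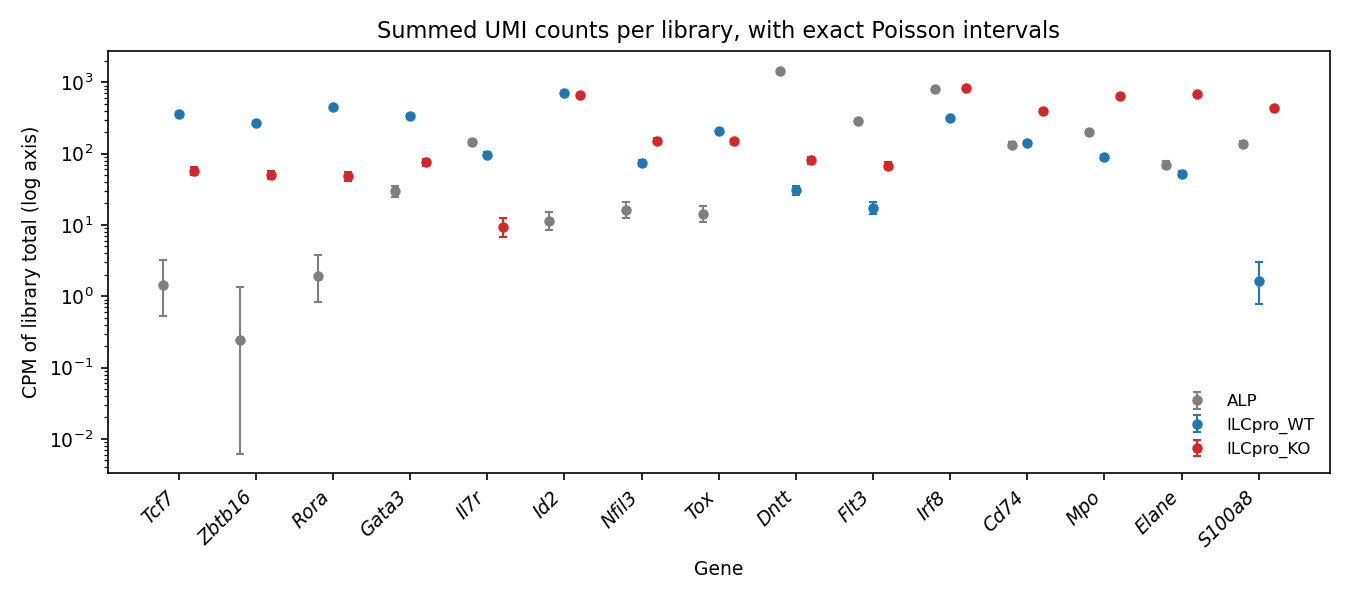
Levels of named genes in the 3 libraries, in CPM of the library total on a log axis, with exact Poisson intervals of counting error. Tcf7 read 362 CPM in ILCpro_WT and 57.3 CPM in ILCpro_KO, while Id2 read 711 and 671 CPM.

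**Figure D2:**
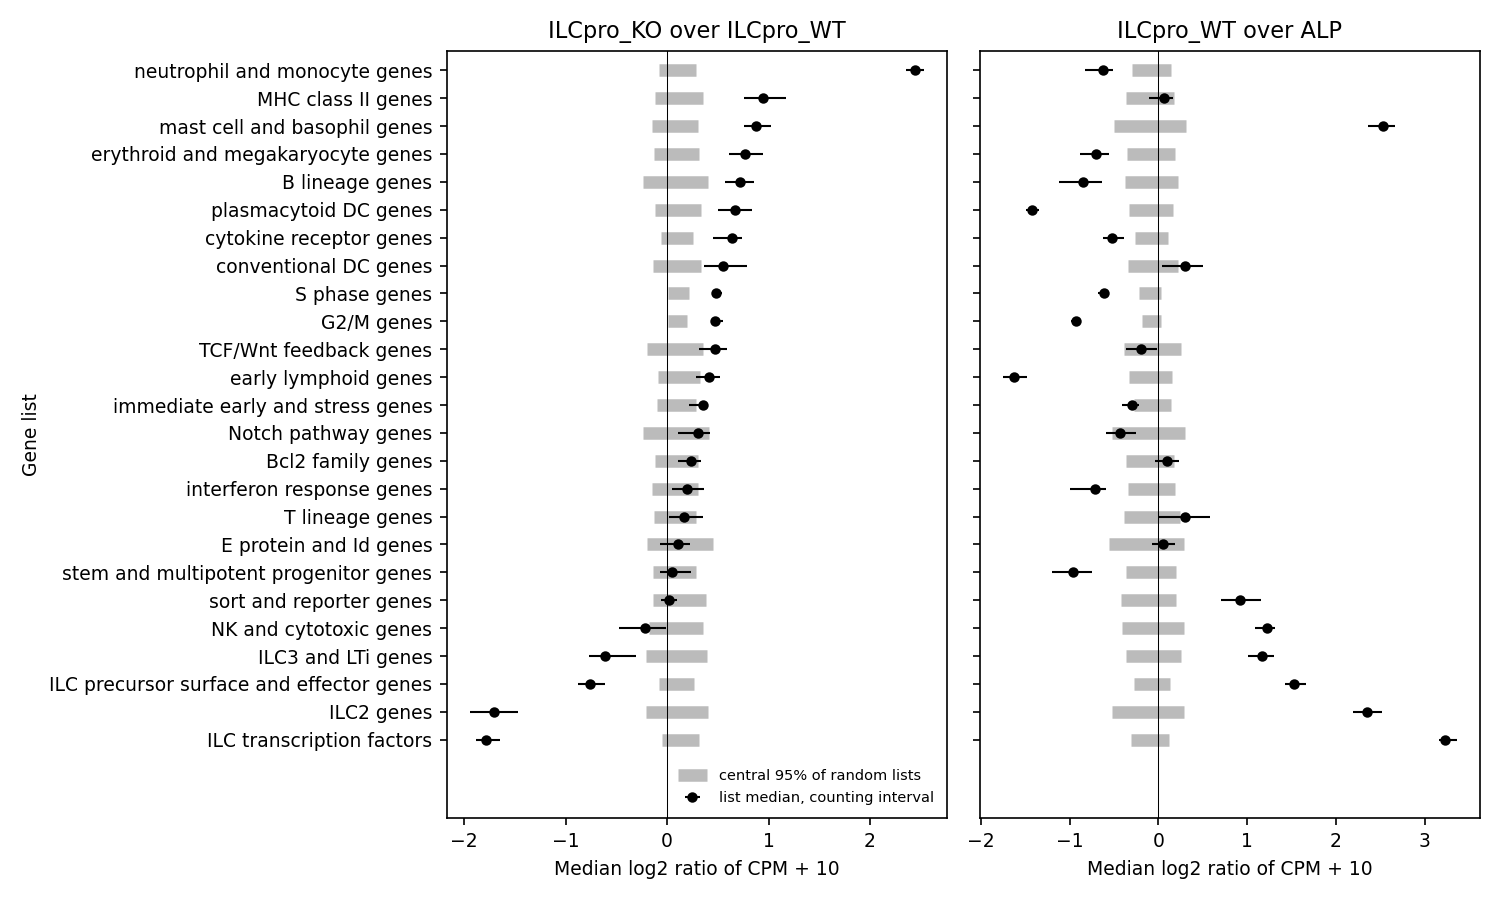
Median log2 ratio of each gene list with at least 3 measured members, for ILCpro_KO over ILCpro_WT and for ILCpro_WT over ALP. Points are list medians with counting intervals and grey bars the central 95% of random lists of like expression; the ILC transcription factors lie at -1.78 on the left and 3.23 on the right.

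Shares of cells with a UMI, thinned to 1000 UMIs, put ILCpro_WT and ILCpro_KO in the same order as the sums for the genes given here. Zbtb16 was found in 22.2% (20.3 to 24.2) of ILCpro_WT cells and 4.19% (2.84 to 5.93) of ILCpro_KO cells, or 45.9% and 18.2% without thinning. In conventional DC-like cells, taken as the background, it was found in 0 of 87 ILCpro_WT cells, which allows up to 3.45%, and in 0.602% (0.0153 to 3.31) of 166 ILCpro_KO cells, an interval that overlaps that of the whole ILCpro_KO library. Rora was found in 30.7% of ILCpro_WT and 3.91% of ILCpro_KO cells (48.8% and 9.78% unthinned), and Il7r in 11.4% and 1.12% (21.6% and 3.63%). In the conventional DC-like cells of ILCpro_KO both were found in 0 of 166, which allows up to 1.81%, so the Il7r share of ILCpro_KO is not told from background. In those of ILCpro_WT Rora was found in 1.15% (0.0291 to 6.24) and Il7r in 0 of 87, which allows up to 3.45%. Id2 was found in 44.6% (42.3 to 46.9) and 40.5% (36.9 to 44.2), against 65.7% and 71.6% unthinned and 2.78% (0.0703 to 14.5) of 36 neutrophil-monocyte-like ILCpro_KO cells at 11278.5 UMIs. Cd74 was found in 4.38% (3.49 to 5.43) of ILCpro_WT and 14.8% (12.3 to 17.6) of ILCpro_KO cells (7.22% and 24.2% unthinned). In unnamed cluster 2 of ILCpro_KO, at a median of 4820 UMIs, it was found in 1.23%. At a depth of 500 UMIs the Tcf7 shares were 16.6% and 2.79% and the Zbtb16 shares 12.7% and 2.37%.

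Clustering of all kept cells without the marker genes gave 15 clusters, numbered by size, and names were given afterwards from the markers. A name therefore rests on those genes, and their levels in a named cluster are no separate result. Clusters 0, 3 and 8 were ILCP-like (like ILC precursors) and held 56.8% (54.5 to 59.1) of ILCpro_WT cells, 5.59% (4.02 to 7.53) of ILCpro_KO cells and 0 of 810 ALP cells, which allows up to 0.370%. In ILCpro_WT these were 554 cells of cluster 0, 422 of cluster 3 and 63 of cluster 8, and in ILCpro_KO 23, 17 and 0. Cluster 8 got the name from Il7r, Gata3, Rora, Il18r1, Cxcr6 and Icos. Zbtb16, Tcf7, Pdcd1 and Id2 were not at least 2-fold higher in it, so the name holds less well there. Conventional DC-like cluster 5 held 4.76% (3.83 to 5.83) of ILCpro_WT and 23.2% (20.1 to 26.5) of ILCpro_KO cells. Its name rests on 7 markers: Batf3, Cst3, Ifi30, H2-Aa, H2-Ab1, H2-Eb1 and Cd74. The other markers of that type, Zbtb46, Itgax, Xcr1, Clec9a and Naaa, were not at least 2-fold higher. Neutrophil-monocyte-like cluster 9 held 0.492% and 5.03% (3.55 to 6.89), NK cell-like cluster 12 held 1.59% and 0.279%, and B cell-like cluster 13 held 0.273% and 0.838%. T cell-like cluster 14 held 22 cells, all from ILCpro_KO. The ILCP-like name moved with the settings, because in 5 of 7 alternatives the counterpart of cluster 0 or cluster 3 stayed unnamed, where Tox2, a marker of EILP, or Ccl5, a marker of NK cells, led. The class held 23.1% to 57.0% of ILCpro_WT cells and 1.12% to 5.87% of ILCpro_KO cells over 7 alternatives, and the conventional DC-like class held 4.32% to 7.05% and 11.5% to 35.1%. Clusters that 1 library fills almost alone, such as 0, 3, 8 and 12 (ILCpro_WT), 14 (ILCpro_KO) and 1 and 6 (ALP), may be that library and not a type.

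Unnamed cluster 2 had similar shares in both ILC progenitor libraries, 20.2% (18.4 to 22.1) of ILCpro_WT and 22.8% (19.7 to 26.0) of ILCpro_KO cells. Among its 10 leading genes were Nfil3, Cpa3, a mast cell protease, Mycn and Itga4, the a4 integrin of the gate. The likeness of the 2 shares depended on the setting. At resolution 1.5 the unnamed cluster led by Nfil3 held 324 ILCpro_WT and 66 ILCpro_KO cells, against 369 and 163 in cluster 2. At resolution 0.5 the cluster led by Nfil3 held 402 and 241. Unnamed cluster 4, led by Bhlhe41, Asb2 and Cd7, with Runx3 among its 10 leading genes, held 5.30% (4.32 to 6.43) of ILCpro_WT and 22.5% (19.5 to 25.7) of ILCpro_KO cells. Its markers pointed to conventional DCs, but a marker of another type led, and by a naming rule whose details were written after the data were seen it stayed unnamed, as did clusters 10 and 11. Cluster 7, led by genes of dividing cells, held 9.24% and 7.96%. Cluster 10, led by the basophil proteases Prss34 and Mcpt8 and by haemoglobin genes, held 0.765% and 3.91%, and cluster 11, led by Lyz2, held 0.219% and 3.63%. The gate asks for Kit and a4b7 in both libraries, and the ILCpro_KO cells were the deeper.

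**Figure D3:**
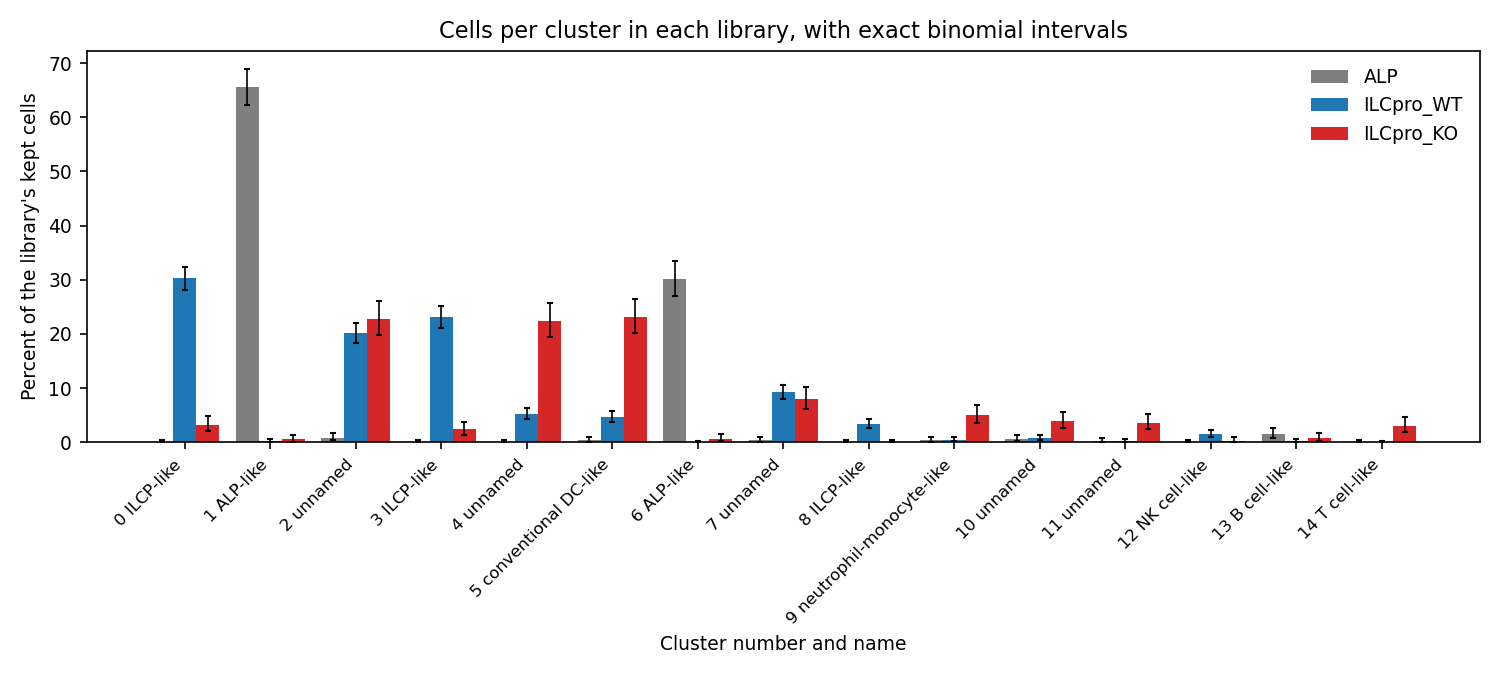
Percent of each library's kept cells in each of the 15 clusters, with exact binomial intervals. Cluster 0 holds 30.3% of ILCpro_WT and 3.21% of ILCpro_KO cells, cluster 5 holds 4.76% and 23.2%, and ALP cells fall mainly in clusters 1 and 6.

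Within the 4 clusters that held at least 50 cells of both libraries, Tcf7 was lower in ILCpro_KO in each: 68.2 (51.9 to 87.9) against 223 CPM (197 to 251) in cluster 2, 154 (127 to 185) against 533 (447 to 630.5) in cluster 4, 5.29 (1.94 to 11.5) against 26.4 (11.4 to 52.0) in cluster 5 and 25.5 (13.97 to 42.9) against 195 (168 to 225) in cluster 7. Rora was also lower in each, at 10.4 against 27.4, 40.3 against 109.7, 3.53 against 23.1 and 5.47 against 145 CPM. Tox2 stood at 5.37 against 145 CPM in cluster 4, and its 1 UMI in cluster 2 of ILCpro_KO gave a 17.2-fold lower level (2.81 to 708). Ikzf2, the factor Helios, was 3.93-fold lower (2.71 to 5.74) in cluster 4 and 2.31-fold lower (1.68 to 3.22) in cluster 7. Flt3 was higher in cluster 2 at 105 (84.6 to 129) against 39.8 CPM (29.3 to 52.8) and in cluster 7 at 93.1 against 22.6 CPM. Dntt was 2.82-fold higher (2.15 to 3.72) in cluster 2 and 2.89-fold higher (2.07 to 4.07) in cluster 7. Nfil3 was 1.52-fold (1.23 to 1.86) and 2.81-fold (2.07 to 3.83) higher there, but 0.847-fold (0.619 to 1.17) in cluster 4. The median of the ILC transcription factors was -0.24, -0.23, -0.20 and -1.12 in clusters 2, 4, 5 and 7, over the 9, 13, 10 and 13 members that reached 20 CPM there. In cluster 5 it lay at the edge of the central 95% of random lists, just inside it, with 2 members at least 2-fold lower, and in the other 3 clusters below that range. Tcf7, the gene altered in ILCpro_KO, counts in each of these medians. In cluster 2 Tcf7 was the single member at least 2-fold lower, and in cluster 5 the 2 were Tcf7 and Rora. In cluster 5, Cst3, a protease inhibitor abundant in DCs, was 2.28-fold lower (2.12 to 2.44) in ILCpro_KO and Cd74 1.59-fold lower (1.42 to 1.77). The higher class II RNA of the whole library thus did not come with a higher level in that cluster. Cluster 5 may pool unlike cells in the 2 libraries. At resolution 1.5 the conventional DC-like cluster held 82 ILCpro_KO and 79 ILCpro_WT cells, against 166 and 87 in cluster 5. An unnamed cluster led by Hp, Anxa3 and Prtn3 held 91 and 14 at that resolution. Clusters 2 and 4 may pool unlike cells too. At resolution 1.5 the cluster led by Nfil3 held 66 ILCpro_KO cells, against 163 in cluster 2. The one led by Bhlhe41 held 110 ILCpro_KO and 48 ILCpro_WT cells, against 161 and 97 in cluster 4. Within cluster 4, 15 of 32 S phase genes were at least 2-fold higher in ILCpro_KO (median 0.96).

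Neutrophil and monocyte genes also had medians above 0 within these clusters, at 0.53, 0.73, 0.80 and 0.98 over 7, 6, 9 and 7 members. Mpo stood at 265 (231 to 301) against 167 CPM (144 to 191) in cluster 2 and at 276 (246 to 308) against 42.9 (22.8 to 73.3) in cluster 5. As given above, cluster 5 may pool unlike cells, so its Mpo levels may not compare like with like. S100a8, which these clusters lacked in ILCpro_WT (0 UMIs), was present in ILCpro_KO at 11.6, 2.68, 13.2 and 14.6 CPM, against 4358 CPM in its neutrophil-monocyte-like cells. Free RNA in the droplets was not measured, so low counts of granule genes are not read as expression by the cells of these clusters.

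**Figure D4:**
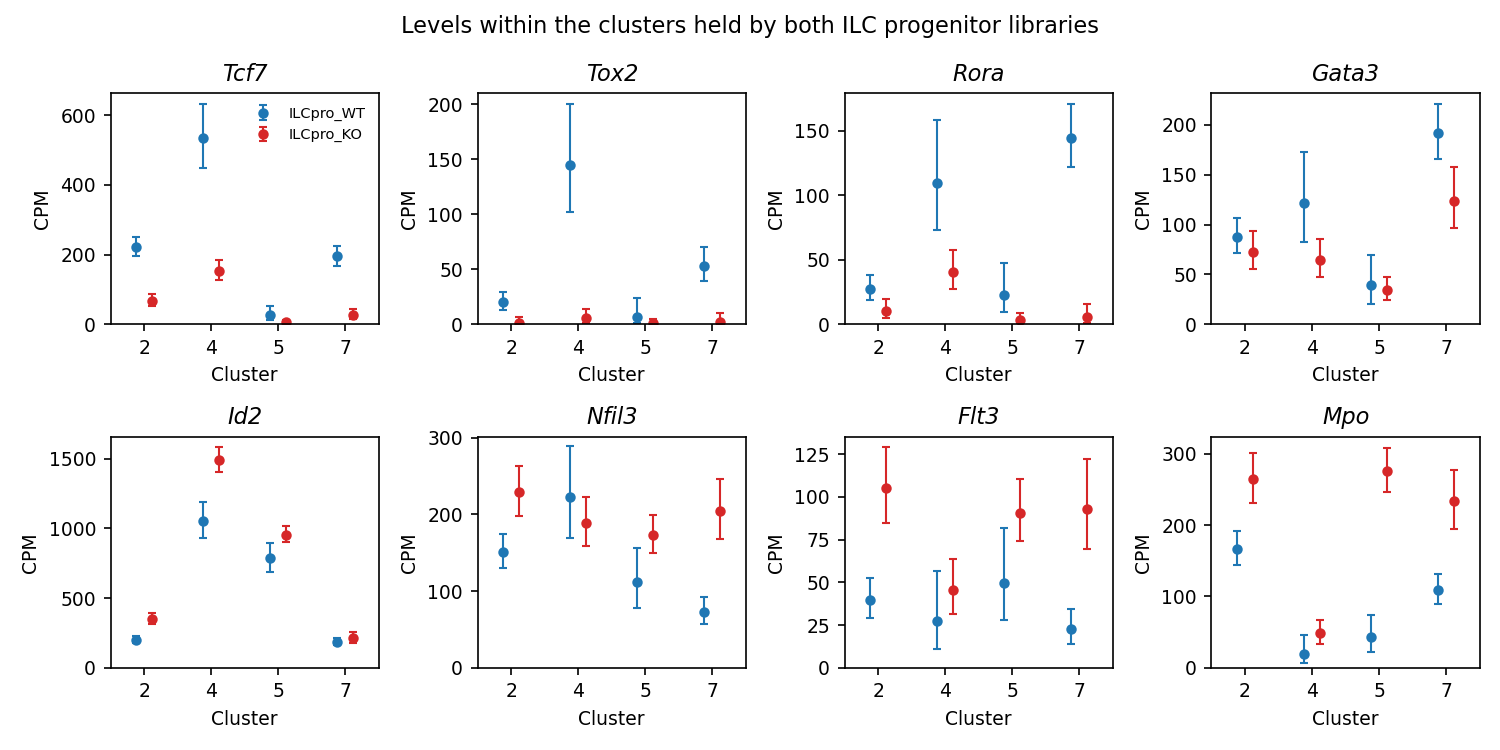
Levels of 8 genes in CPM within clusters 2, 4, 5 and 7 of ILCpro_WT and ILCpro_KO, with exact Poisson intervals; each vertical axis starts at 0. In cluster 2 Tcf7 reads 223 CPM in ILCpro_WT and 68.2 CPM in ILCpro_KO, and Flt3 reads 39.8 and 105 CPM.

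Genes of the cell cycle were a little higher in ILCpro_KO than in ILCpro_WT. The 40 S phase genes had a median of 0.49 with 2 at least 2-fold higher, such as Rrm2 at 107 against 44.96 CPM, and the 54 G2/M genes had a median of 0.47 with none at least 2-fold higher. Phase calls, which also follow depth and free RNA, put 36.9% of ILCpro_KO and 61.6% of ILCpro_WT cells in G1, and no cycling is read from them. Of the gate's own genes, Kit, the stem cell factor receptor, stood at 22.8 against 66.1 CPM, and the 7 sort and reporter genes had a median of 0.02, which was -0.12 with TMM scaling, and a mean of -0.46.

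The labels name early ILC progenitors (EILP) and ILC precursors, and the 1 gate of ILCpro_WT can hold both. Within this library the clusters differed in genes used here as markers of these stages. The markers were left out of the clustering but gave the names, so the levels describe the named clusters. Zbtb16 stood at 76.3 CPM (61.5 to 93.6) in unnamed cluster 2, 363 (332 to 396) in ILCP-like cluster 3 and 598 (559.5 to 639) in ILCP-like cluster 0. Gata3 stood at 87.9, 308 and 712 CPM and Id2 at 201, 542 and 1615 CPM in the same order. Il7r was alike in clusters 2 and 3, at 19.9 (12.8 to 29.6) and 25.7 CPM (18.0 to 35.6), and reached 287 CPM (260.1 to 315) in cluster 0. Ets1 stood at 4.98, 40.0 and 327 CPM and Il18r1, an interleukin 18 receptor chain, at 61.4, 27.8 and 581 CPM. Nfil3 ran the other way, at 151 (129.8 to 175), 43.5 (33.3 to 55.9) and 23.4 CPM (16.3 to 32.6), as did Flt3 at 39.8, 6.42 and 2.68 CPM. Irf8 stood at 598, 87.8 and 60.3 CPM and Mpo at 167, 12.8 and 4.69 CPM. Cluster 8 had Gata3 at 1137 CPM, Icos at 434 CPM and the ILC2 receptors Il1rl1 and Il17rb at 48.3 and 91.2 CPM, with Zbtb16 at 16.1 (3.32 to 47.0) and Tcf7 at 59.0 CPM (29.4 to 106). Cluster 4 had Tcf7 at 533 and Id2 at 1054 CPM, with Zbtb16 at 118 CPM. Clusters 2, 3, 0, 8 and 4 of this library had median depths of 3160, 2928.5, 2295, 2845 and 2190 UMIs.

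ILCpro_WT against ALP asks what sets early ILC progenitors apart from the lymphoid progenitor. The genotype is the same and the gate differs, so the genes of the gate (Flt3, Il7r, Itga4, Itgb7 and the Tcf7 reporter) differ by the sort itself. ILC regulators were far higher in ILCpro_WT: Tcf7 at 362 against 1.46 CPM, Rora at 449 against 1.94 CPM, 231-fold (117 to 536), and Id2 at 711 against 11.4 CPM, 62.2-fold (46.7 to 84.8). Zbtb16 had 1 UMI in ALP and was 1114-fold higher (199.7 to 44035), and Tox2 had 0 and was at least 302-fold higher. Genes of the early lymphoid programme were lower, led by Dntt at 30.5 (26.3 to 35.2) against 1452 CPM (1415 to 1489), 47.6-fold lower (41.1 to 55.4).

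All 14 measured ILC transcription factors were at least 2-fold higher in ILCpro_WT, with a median log2 ratio of 3.23 (3.17 to 3.37), and 3.29 with members at 0 UMIs set to their bound. Of 15 surface and effector genes 12 were at least 2-fold higher (median 1.53, or 1.56 at the bound), such as Pdcd1, a receptor of ILC precursors, at 123 against 2.19 CPM and Thy1 at 71.9 against 0.972 CPM. These medians were 5.19 and 2.76 with a pseudocount of 1 CPM. Other genes with large ratios were Ccl5 at 1267 against 3.64 CPM (348-fold, 211 to 622), Ikzf2 at 383 against 26.0 CPM, Lmo4 at 595 against 45.7 CPM, Bcas1 at 141 against 2.92 CPM, Fgf3 with 3 UMIs in ALP (193-fold, 65.9 to 939) and Rxrg with 0 (at least 132-fold). All 4 ILC2 genes (median 2.35) and 4 of 6 ILC3 and LTi genes (median 1.17) were at least 2-fold higher, with Ltb at 167 against 24.0 CPM. With no list minimum these medians were 0.24 and 0.17, and that of NK and cytotoxic genes 0.35. With the minimum, NK and cytotoxic genes had a median of 1.23, or 1.54 at the bound, with Nkg7 at 361 against 117 CPM. Bcl2, a survival factor, stood at 1219 against 263 CPM, the single Bcl2 family gene of 9 that was at least 2-fold higher.

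Of 13 early lymphoid genes 8 were at least 2-fold lower in ILCpro_WT (median -1.62), with Flt3 at 17.6 against 288 CPM, Cnn3 at 18.9 against 232 CPM and Mef2c at 206 against 798 CPM. Plasmacytoid DC genes were lower too (median -1.43, 7 of 10), with Cox6a2 at 17.7 against 385 CPM and Siglech at 0.492 CPM from 3 UMIs against 23.8 CPM (48.4-fold lower, 16.1 to 239). B lineage genes had a median of -0.85, or -1.74 in G1 cells, with the adaptor Blnk at 0.328 CPM from 2 UMIs against 49.1 CPM (149.6-fold lower, 40.9 to 1243). Egfl7, Myl10, Clec12a, Il12a, Lmo2 and Wfdc17 were 13.1-fold, 9.77-fold, 10.8-fold, 10.3-fold, 12.5-fold and 24.4-fold lower. S100a8 was 83.2-fold lower (44.9 to 175) at 1.64 against 137 CPM, and S100a9 had 2 UMIs in ILCpro_WT (213-fold lower, 58.3 to 1763). Without other lineages the log2 ratio of S100a8 was -0.65 in place of -3.65, and that of S100a9 -0.33 in place of -2.95. Cell cycle genes were lower, with 20 of 54 G2/M genes at least 2-fold lower (median -0.93, or -0.21 in G1 cells) and 2 of 40 S phase genes (median -0.62). Conventional DC genes had a median of 0.30, which was -0.02 as a mean of per-cell CPM, -0.11 in G1 cells and -0.01 without the minimum on expression. Zbtb16 was found in 0 of 810 thinned ALP cells, which at this depth allows up to 0.370% of cells with a UMI, and Dntt in 68.1% (64.8 to 71.3) of them against 2.41% (1.76 to 3.22) of ILCpro_WT cells. Without thinning Dntt was found in 90.7% and 6.12%. In cluster 0 of ILCpro_WT Dntt was found in 0.726% at 2302 UMIs, and ALP had no group of at least 20 cells to serve as a background, since its larger clusters are ALP-like. ALP-like clusters 1 and 6 held 95.7% of ALP, 0.383% of ILCpro_WT and 1.26% of ILCpro_KO cells.

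ILCpro_KO against ALP completes the 3 pairs, and here genotype and gate both differ and neither can be separated. Part of the ILC programme was present in ILCpro_KO at levels far above ALP: Id2 at 671 against 11.4 CPM (58.7-fold, 44.0 to 80.1), Tox, needed for early ILC progenitors, at 149 against 14.3 CPM (10.4-fold) and Nfil3 at 153 against 16.3 CPM (9.37-fold). Id2 is also a member of the conventional DC list and counts in its median given below. Conventional DC-like cells took 23.2% of ILCpro_KO and 0.370% of ALP, so Id2 is not particular to ILC progenitors here. Of 14 ILC transcription factors 13 were at least 2-fold higher, with a median of 2.42 (2.24 to 2.51), or 2.59 at the bound and 3.77 with a pseudocount of 1 CPM. Lef1, a relative of Tcf7, had 1 UMI in ALP and was 325-fold higher (57.9 to 12866). It was among the 10 leading genes of T cell-like cluster 14, which was found in ILCpro_KO alone. Il7r, which the ALP gate selects, was 15.6-fold lower (11.3 to 21.9) at 9.35 against 145.5 CPM, and Dntt was 18.1-fold lower (16.2 to 20.2) at 80.3 against 1452 CPM.

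Early lymphoid genes had a median of -1.04 with 7 of 13 at least 2-fold lower, and plasmacytoid DC genes -1.01 with 5 of 10. Cox6a2, Myl10, Egfl7, Cmah, Sdc1, Arpp21, Samsn1 and Tspan13 were 14.3-fold, 11.1-fold, 10.8-fold, 34.4-fold, 28.9-fold, 8.26-fold, 6.50-fold and 6.11-fold lower. Surface and effector genes had a median of 1.53 with 7 of 12 at least 2-fold higher and 2 at least 2-fold lower, and a median of 0.71 with no list minimum. Cd7 stood at 90.8 against 8.75 CPM and Itgb7, a part of the a4b7 gate, at 162 against 24.3 CPM. Neutrophil and monocyte genes had a median of 1.63 (0.80 in G1 cells) with 10 of 15 at least 2-fold higher, such as Elane at 675 against 69.7 CPM and Prtn3, 7.31-fold higher, and Mcpt8, Cpa3, Hp and S100a4 were 16.6-fold, 21.4-fold, 15.5-fold and 14.4-fold higher. Without cells of other lineages, an alternative chosen after seeing the data, the neutrophil and monocyte median was 0.47 and the log2 ratio of Lyz2 changed from 1.79 to -1.35, while that of Elane was 1.78 in place of 3.10 and that of Mcpt8 1.84 in place of 3.53. MHC class II genes had a median of 0.85, with Cd74 at 397 against 134 CPM, and conventional DC genes 0.97, with Batf3, a regulator of conventional DCs, at 40.6 CPM against 0 UMIs, at least 55.7-fold higher. Without those cells, which include the B cell-like ones of ALP, the log2 ratio of Cd74 was 3.436 in place of 1.4998.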

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

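No paired analysis was possible because each group has 1 library and nothing pairs the cells, and no replicate could be left out. The removal of clusters of other lineages was chosen after seeing the data; the other alternatives were planned. The main results (the list medians of the next paragraphs up to the reversals, the shares of Tcf7 and Zbtb16 and the shares of ILCP-like and conventional DC-like cells) kept their direction under every alternative run. For lists, 74 values of these stayed within counting error and 47 moved beyond it; for shares of cells with a UMI 6 and 14, and for classes of clusters 13 and 15. Of the other values, 851 of genes, 492 of lists, 184 of shares and 111 of classes stayed, 353, 231, 186 and 8 moved, and 2 of genes and 13 of lists reversed. Reversal is counted for genes at least 2-fold apart and for list medians outside the central 95% of random lists. Of the values inside these limits, 9 of the genes and 20 of the lists that moved also changed sign, as did 4 of genes and 7 of lists within counting error. Where no reason is given, the cause was not tested.

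Among ILCpro_KO over ILCpro_WT medians, the ILC transcription factors (reported as -1.78) ran from -1.98 to -1.47. Their median was -1.91 with TMM, -1.89 without ribosomal and mitochondrial genes in the totals, -1.55 with the stricter filter, -1.47 in G1 cells, -1.98 with a pseudocount of 1 CPM and -1.94 without other lineages. Surface and effector genes (-0.76) had -0.90 without ribosomal and mitochondrial genes, -0.52 with the stricter filter, -0.60 in G1 cells and -0.97 with the pseudocount of 1 CPM. Early lymphoid genes (0.41) had 0.28 with TMM, 0.55 in G1 cells and 0.52 without other lineages. Conventional DC genes (0.55) had 0.82 with the pseudocount, 0.81 with a list minimum of 20 CPM and 0.29 with none, and MHC class II genes (0.94) had 1.34 in G1 cells and 1.35 with the pseudocount. Neutrophil and monocyte genes (2.45) had 2.31 with TMM, 2.28 as a mean of per-cell CPM, 2.29 with the stricter filter, 1.76 in G1 cells, 2.83 with the pseudocount, 2.72 with the minimum of 20 CPM, 1.94 with none and 1.21 without other lineages, a setting that removes clusters 9 and 11, led by such genes, among others.

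For ILCpro_WT over ALP, the ILC transcription factors (3.23) had 3.65 without ribosomal and mitochondrial genes, 3.54 as a mean of per-cell CPM, 3.02 with the stricter filter, 3.37 in G1 cells, 5.19 with the pseudocount of 1 CPM, which by its construction widens ratios of genes near 0, and 3.14 with no list minimum. Surface and effector genes (1.53) had 1.93, 1.71 and 1.42 under the first 3 of these settings and 2.76 with the pseudocount. Early lymphoid genes (-1.62) had -2.17 in G1 cells and -1.95 with the pseudocount. For ILCpro_KO over ALP, the ILC transcription factors (2.42) had 2.65 without ribosomal and mitochondrial genes, 2.64 as a mean of per-cell CPM, 2.78 in G1 cells, 3.77 with the pseudocount, 2.56 with the minimum of 20 CPM and 2.74 without other lineages. Early lymphoid genes (-1.04) had -1.23 in G1 cells, -1.28 with the pseudocount and -0.90 without other lineages.

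The values that reversed, all beyond those limits, were these. In ILCpro_KO over ILCpro_WT, NK and cytotoxic genes had 0.029 in G1 cells and 0.041 with the minimum of 20 CPM, ILC3 and LTi genes 0.31 in G1 cells, and, without other lineages, erythroid and megakaryocyte genes -0.41 and Hba-a1 -0.13. In ILCpro_WT over ALP, T lineage genes had -0.030 in G1 cells, and conventional DC genes -0.022 as a mean of per-cell CPM, -0.11 in G1 cells and -0.011 with no list minimum. In ILCpro_KO over ALP, T lineage genes had -0.0355 without other lineages, erythroid and megakaryocyte genes -0.22 with all deposited barcodes, -0.21 in G1 cells and -0.19 without other lineages, S phase genes 0.04 in G1 cells, and Lyz2 -1.35 without other lineages, a setting that removes cluster 11, which Lyz2 led.

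Medians within the central 95% of random lists also moved with a change of sign. In ILCpro_KO over ILCpro_WT, E protein and Id genes (0.11) had -0.12 with TMM, T lineage genes (0.17) -0.295 without other lineages, Bcl2 family genes (0.24) -0.035 in G1 cells, and sort and reporter genes (0.02) -0.12 with TMM and -0.083 without ribosomal and mitochondrial genes. In ILCpro_WT over ALP, TCF/Wnt feedback genes (-0.19) had 0.56 with TMM, 0.75 without ribosomal and mitochondrial genes, 0.60 as a mean of per-cell CPM, 0.55 in G1 cells and 0.11 with no list minimum, while the minimum of 20 CPM gave -1.10; Notch pathway genes (-0.43) had 0.076 with the minimum of 20 CPM, and MHC class II genes (0.06) -0.45 as a mean of per-cell CPM and -0.84 in G1 cells. In ILCpro_KO over ALP, Notch pathway genes (0.38) had -0.25 with TMM, -0.23 with the stricter filter, -0.54 with the minimum of 20 CPM and -0.22 without other lineages, and E protein and Id genes (0.31) had -0.065, -0.052 and -0.053 under TMM, the minimum of 20 CPM and without other lineages. Genes less than 2-fold apart that did so were Id2, Rag1 and Cpa3 in ILCpro_KO over ILCpro_WT, Cd74 and Cd79a in ILCpro_WT over ALP, and Cd79a and Kit in ILCpro_KO over ALP. Cd74 in ILCpro_WT over ALP, reported as 0.06, ran from -1.63 in G1 cells up to 1.91 over the alternatives.

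Other list medians moved far without a change of sign. In ILCpro_WT over ALP the pseudocount of 1 CPM gave 2.48 for NK and cytotoxic genes (1.23), 3.08 for ILC2 genes (2.35), 2.53 for ILC3 and LTi genes (1.17), 3.33 for mast cell and basophil genes (2.54), -1.67 for B lineage genes (-0.85) and -1.98 for stem and multipotent progenitor genes (-0.96). The minimum of 20 CPM gave 3.14 for ILC2 genes, 1.94 for ILC3 and LTi genes and -1.63 for B lineage genes there. In ILCpro_KO over ALP the pseudocount gave 2.36 for surface and effector genes (1.53) and 2.07 for ILC2 genes (0.86), which had 1.69 with the minimum of 20 CPM.

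Shares follow depth by construction. The Tcf7 share of ILCpro_WT and ILCpro_KO was 54.3% and 22.2% without thinning and 16.6% and 2.79% at 500 UMIs, and the Zbtb16 share 45.9% and 18.2%, and 12.7% and 2.37%. In G1 cells Tcf7 had 36.0% and 9.47% and Zbtb16 31.3% and 6.44%. With the stricter filter the ILCpro_WT shares were 25.2% for Tcf7 and 19.9% for Zbtb16.

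ILCP-like cells took 25.9% of ILCpro_WT and 2.10% of ILCpro_KO with cell cycle genes kept, 26.4% and 1.12% with doublets removed, 23.1% and 3.21% with markers kept, 27.9% and 2.10% at resolution 0.5 and 23.7% and 1.26% when cells were thinned first. In each of these a cluster with most of its markers of that type stayed unnamed. Conventional DC-like cells took 12.8% of ILCpro_KO with markers kept, 11.5% at resolution 1.5, 13.97% when cells were thinned first and 35.1% at resolution 0.5, where they took 7.05% of ILCpro_WT. TMM scaling moved the median of all genes for ILCpro_KO over ILCpro_WT from 0.09 to -0.02, and the list medians above are to be read beside that shift.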

Other observations

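The tests of explanations in the last 3 paragraphs of this part were chosen only after the results they measure had been seen, although the gene lists and the clustering of thinned cells that they use had been planned. In ILCpro_KO over ILCpro_WT, TCF/Wnt feedback genes had a median log2 ratio of 0.47 (0.32 to 0.59) over 6 members, none at least 2-fold apart. Lef1, the relative of Tcf7 that binds the same sites, stood at 78.9 against 44.5 CPM. Lef1 was among the 10 leading genes of T cell-like cluster 14, whose 22 cells were all from ILCpro_KO, so these cells raise its level there. E protein and Id genes had 0.11 and stem and multipotent progenitor genes 0.05, which were -0.12 and -0.03 with TMM scaling. Bcl2 family genes had 0.24, immediate early and stress genes 0.35 and interferon response genes 0.20. Among the last, Ifitm3, an antiviral membrane protein, stood at 124 against 22.3 CPM. It was among the 10 leading genes of cluster 11, led by Lyz2, which held 26 ILCpro_KO and 4 ILCpro_WT cells. B lineage genes had 0.72 over 4 members, with Ebf1, which starts the B lineage, at 17.3 against 5.58 CPM. Cytokine receptor genes had 0.64 over 16 members that went both ways, with Il2rg, the common gamma chain, at 40.1 against 104 CPM. NK and cytotoxic genes had -0.22 over 7 members, with Gzma, a granzyme, at 31.0 against 2.46 CPM and Eomes at 2.74 against 9.02 CPM. Gzma, too, was among the 10 leading genes of T cell-like cluster 14. Of the macrophage genes Cd68 alone passed the list minimum, at 24.2 against 7.71 CPM.

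In ILCpro_WT over ALP, TCF/Wnt feedback genes had a median of -0.19, which was 0.56 with TMM scaling, 0.75 with totals without ribosomal and mitochondrial genes and -1.10 over 4 members with a list minimum of 20 CPM. Notch pathway genes had -0.43, with Hes1 at 46.9 against 1.22 CPM and Notch1 at 24.3 against 111 CPM, and interferon response genes -0.72. Stem and multipotent progenitor genes had -0.96, or -1.72 with a list minimum of 20 CPM, with Mycn at 112 against 16.5 CPM and Hoxa9 at 16.4 against 96.2 CPM. MHC class II genes had a median of 0.06 and a mean of -0.15, and the median was -0.84 in G1 cells. Mast cell and basophil genes had 2.54, or 0.85 without other lineages, 0.27 in G1 cells and 0.17 with no list minimum, and cytokine receptor genes -0.52. In ILCpro_KO over ALP the median and mean differed in sign for TCF/Wnt feedback genes (-0.14 and 0.28), Notch pathway genes (0.38 and -0.15, with a median of -0.25 under TMM scaling) and cytokine receptor genes (0.00 and -0.17). ILC2 genes had 0.86 there, or 1.69 with members at 0 UMIs set to their bound, mast cell and basophil genes 1.09 or 2.01, and stem and multipotent progenitor genes -0.74 or -0.95. The median of the mast cell and basophil genes was 3.53 over 3 members with a list minimum of 20 CPM, 3.28 with a pseudocount of 1 CPM and 1.72 in G1 cells.

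The ILC transcription factors were lower in ILCpro_KO, and 9 were at least 2-fold lower. Dilution by the cells of clusters 9, 10, 11, 13 and 14 is excluded, since without them the median of the 9 was -2.32 (-2.46 to -2.16), against -2.03 with them; conventional DC-like cluster 5 and cluster 4 stayed in and belong to the mix that follows. A different mix of the clusters, each at its ILCpro_WT level, predicted -1.39, and the observed median lay at -0.55 (-0.69 to -0.48) against that prediction, or -0.41 at resolution 1.5; clusters with too few ILCpro_WT cells entered at their own level, 127 and 214 ILCpro_KO cells, which draws the prediction toward the observation. For the 9 genes as a set a different mix and a lower level within cells cannot be told apart. The median gap was under 2-fold, and the 9 genes were picked as lower in these same libraries. All 9 lay below the main prediction, and 8 of 9 below that at resolution 1.5. Tox2 lay at -1.51 and -1.23 against the predictions of the 2 clusterings. Tcf7 lay at -1.60 and -1.56, but it is itself the gene altered in ILCpro_KO and says nothing of the other members. The loss of Tcf7, by either route, may be the cause and stays open as an untested biological explanation, with 1 library per genotype.

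MHC class II genes and conventional DC-like cells were higher in ILCpro_KO. Free RNA spread over all cells is excluded as the whole cause, since 4 summed class II genes stood 468.7 CPM higher in ILCpro_KO than in ILCpro_WT, but at 72.8 CPM in its cluster 2, 0.155 of that excess (0.110 to 0.216), and at 29.7 CPM in its neutrophil-monocyte-like cells. The greater depth of ILCpro_KO is excluded as the whole cause: with cells thinned before clustering the share was 13.97% (11.5 to 16.7) against 5.59% (4.58 to 6.74), and the lower bound over the upper was 1.71. Within cluster 5 the summed class II level in CPM was not higher in ILCpro_KO, with a ratio to ILCpro_WT of 0.682 (0.627 to 0.744). This cannot exclude more class II RNA per conventional DC-like cell. CPM is relative to all UMIs, and ILCpro_KO cells of cluster 5 were deeper, at a median of 6546 against 3141 UMIs. At resolution 1.5 the conventional DC-like cluster held 82 ILCpro_KO and 79 ILCpro_WT cells, against 166 and 87 in cluster 5. Cluster 5 may therefore pool unlike cells in the 2 libraries. More conventional DC-like cells in the gate could come from the genotype or from a difference between sorts, and neither was tested.

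T cell-like cells were seen in ILCpro_KO alone, 22 of 716 cells against 0 of 1829 in ILCpro_WT, which allows up to 0.164%. By counting error alone, too few cells sampled in ILCpro_WT is excluded, as that limit was 0.0847 of the lower bound in ILCpro_KO (0.104 with the exact upper bound). The gate genes summed to 30.2 CPM, from 3 UMIs, in these cells against 774 CPM in the other cells, a ratio of 0.0391 (0.00805 to 0.114), which excludes doublets of a T cell and a gated progenitor. That low ratio is consistent with cells from outside the sort gate. A change of fate in cells without Tcf7 stays open and was not tested.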
